A study of Rattus norvegicus with 6 samples.

How the data were processed

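RNA from whole rat hearts was measured on 6 Clariom S Rat microarrays, single-channel Affymetrix arrays that summarise the probes of a transcript into 1 value per transcript cluster. The labels put 2 arrays in each of 3 groups: normal hearts, hearts under TAC, and TAC-R hearts, which the design text describes as released from TAC. The surgical protocol in the labels describes a silk thread tied around the transverse aorta over a blunt needle, so TAC is a narrowing of the aorta that loads the left ventricle. The animals were male Sprague-Dawley rats. That protocol also mentions control rats operated on without the ligature, and the labels do not say whether the normal hearts came from such rats or from rats without surgery. The time under TAC, the time after release, and any array batch or scan date are not given in the sources used here. The labels do not say whether the 2 arrays of a group came from different animals, so the p-values measure only the spread between these arrays, which may be technical. The extraction field of the labels speaks of cultured fibroblasts and a purification kit for PCR products, whereas every other field speaks of whole heart. The arrays are described here as whole heart on the strength of those other fields. The heart muscle genes Actc1, Mb, Myl3 and Pln had the highest value in the data on all 6 arrays, which argues against cultured fibroblasts.

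The values used were the deposited log2 signals, 1 column per array. Per the labels, the authors made them with robust multi-array averaging (RMA) in Expression Console at the level of core exons, and the design text names an Affymetrix computational tool. Software versions and background settings are not given in the sources used here. The deposited log2 values were used without further scaling. They had closely similar quartiles on all arrays, with medians from 5.31 to 5.39, and stopped at a ceiling of 19.9315, which is the log2 of 1e+06. At that ceiling on all 6 arrays lay 17 rows, among them Actc1, Mb, Myl3, Tpm1, Atp2a2, Slc25a4 and Pln, so no difference could be measured for them. A further 4 rows, among them Hba-a1, Myh7 and Acta1, were at the ceiling on some arrays, and their differences are lower bounds wherever the brighter group is at the ceiling. RMA makes the distributions of the arrays alike, so a shift of all transcripts in 1 direction cannot be seen. The files hold no detection calls. The negative control rows had a median of 4.47 and a 95th percentile of 8.18 over the row means, and tested rows below that percentile are dim. The row means of the tested rows had a median of 5.32, so most tested rows are dim. Called genes with a symbol were held against the percentile of each array, and other genes mostly were not. A printed difference of a gene that was not called may thus lie between signals in the background, with a size that is not measured.

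The table had 24834 rows. Control rows were left out (1153 negative, 399 positive, 63 ERCC and 31 AFFX, 1646 in all), which left 23188 rows for the tests. A platform table gave 1 gene symbol to 15049 of them, several symbols to 0 and none to 8139, which are called unnamed. Updating the symbols through a table of rat genes changed 0 of them. Of the tested rows, 443 had values identical to those of another row on every array, so counts of rows are not counts of independent genes. Probes for globins and for families such as Ifi27 can bind transcripts of related genes, so the members of such families are uncertain as separate genes. Myh6 and Lox, which were among the genes chosen for description, had no named row.

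Differences were tested with limma's linear model and empirical Bayes moderation. It was fitted to all 6 arrays with 1 mean per group, with 3 residual degrees of freedom and no covariate. The moderation had a prior of 5.71 degrees of freedom and a prior standard deviation of 0.250. The rows at the ceiling on all arrays have no spread and lower that prior, which was 7.11 degrees of freedom without them. A row was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 23188 rows in a comparison, with no fold minimum and no filter on dim rows. Differences are on the log2 scale, ± the standard error of the model, and group levels are means ± SD of 2 arrays. With 2 arrays against 2, an exact two-sided permutation test cannot go below p = 0.33, so single genes rest on the pooled spread of the model.

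For gene lists, 54 lists (31 pathways and 23 sets of cell type markers) were tested with limma's camera, 2-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Each of the 15037 genes entered with 1 row, the one with the highest mean. Lists share members. Each list was also tested with a correlation estimated from these arrays and with fry. With an estimated correlation camera uses only the 3 residual degrees of freedom, which raises p even where the correlation is near 0.01. Fry asks whether the genes of a list move on balance in 1 direction, and does not compare the list with other genes. The groups, comparisons, tests, gene lists, named genes and the other settings tried were chosen before the data were examined, and leaving out the control rows was not among those choices. Named in each comparison were the 10 genes with the largest called rise and the 10 with the largest called fall, as far as that many passed with both arrays of a group above both arrays of the other. A fixed set of cardiac stress and matrix genes and up to 4 leading members of each described list were named as well.

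A remaining share, the TAC-R minus normal difference relative to the TAC minus normal difference, was estimated. It used the 500 rows that differed most between a pair of arrays, 1 TAC and 1 normal. The slopes of the TAC-R minus normal and the TAC minus normal differences of those rows were then taken in the other arrays. The mean over the 4 ways of choosing the pair is reported, with their range and without a test.

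The steps were tested on simulated arrays with known changes. In the TAC against normal comparison, planted differences of 1, 1.5, 2 and 3 log2 units were recovered in 12%, 56%, 84% and 100% of 50 rows each, with 4 false calls among 23188 rows. In the TAC-R against TAC comparison these shares were 10%, 54%, 96% and 100%, with 11 false calls. The number of arrays therefore limits the precision, and most differences of 2-fold would be missed. The simulated rows had independent normal noise, with spreads drawn from the prior of the model itself. The false calls therefore do not test whether the real rows meet these assumptions. A list shifted by 0.6 log2 units was found by camera in both comparisons (adjusted p = 3.25e-13 and 4.17e-16) with 0 other lists called. It was missed with the estimated correlation (adjusted p = 0.383 and 0.289) and by fry (0.184 and 0.134). The simulated genes were independent of each other, so camera was not tested on lists whose genes are correlated. A planted remaining share of 0.4 came back as 0.391.

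The other settings tried were an intensity trend or a robust fit in the moderation, the replicate number as a block, filters on dim rows, quantile normalization again, centring of each array, array weights, fits to only the 2 groups compared, other thresholds, and leaving out each array in turn. After the data had been seen, alternatives were added, namely fits without the rows at the ceiling on all arrays and fits with the control rows kept in. R 4.3.3 with limma 3.58.1 was used for the tests, and Python 3.11.15 with matplotlib 3.10.9 for the plots.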

Results

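Whole-heart RNA of rats was profiled on 6 microarrays, 2 from normal hearts, 2 from hearts under TAC, a surgical narrowing of the transverse aorta, and 2 from TAC-R hearts, which had been released from it. Each array correlated most highly with the other array of its own group, at 0.993 across rows for the normal pair, 0.993 for the TAC pair and 0.991 for the TAC-R pair. Correlations between groups were almost as high, up to 0.9908 between normal replicate 1 and TAC replicate 2. TAC-R replicate 1 reached 0.9907 with normal replicate 1, against 0.9913 with TAC-R replicate 2. The first 2 principal components held 28.4% and 26.0% of the variance. The medians of the log2 signals lay between 5.31 and 5.39. Groups are named as the labels name them, and every direction is a difference between arrays carrying those labels.

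The first comparison asked how hearts under TAC differed from normal hearts. On the arrays labelled TAC, the red cell genes Alas2, Slc4a1, Hbb-b1 and Hbb-bs and the interferon-induced genes Usp18, Ifi27, Irf7 and Mx1 rose, and Nppb and Myh7 fell. Alas2, the first enzyme of haem synthesis in red cell precursors, was at least 2.49-fold higher at 9.81 ± 0.23 against 6.79 ± 0.02 log2 units (mean ± SD, n = 2 each, adjusted p = 0.00341), the normal signals lying below the 95th percentile of the negative controls of their arrays, which served as floor for the fold. Slc4a1, the anion exchanger of the red cell membrane, rose by 2.53 ± 0.21 log2 units (adjusted p = 0.00341), and the beta-globin genes Hbb-b1 and Hbb-bs rose by 2.83 ± 0.24 and 2.87 ± 0.25 (adjusted p = 0.00341 and 0.00344). Nppb, which encodes the B-type natriuretic peptide secreted by stretched heart muscle, fell by 2.16 ± 0.24 log2 units, 4.47-fold, from 15.88 ± 0.23 to 13.72 ± 0.22 (adjusted p = 0.0118). Myh7, the slow myosin heavy chain, fell by 2.10 ± 0.20 (adjusted p = 0.00627), and 1 of the normal arrays was at the ceiling for it, so this fall is a lower bound.

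Among the genes with the largest rises on the TAC arrays were also Lgals5, a galectin (3.55 ± 0.39 log2 units, adjusted p = 0.0114), and Alox15, which oxidises arachidonic acid (3.23 ± 0.25, adjusted p = 0.00341). Bdh1, a mitochondrial enzyme of ketone body use, rose by 2.79 ± 0.22 at a high signal of 17.29 ± 0.18 (adjusted p = 0.00341). Chrna1, a subunit of the muscle acetylcholine receptor, rose by 2.66, Wfdc1 by 2.65 and Ephx2, soluble epoxide hydrolase, by 2.43 (adjusted p = 0.00703, 0.00737 and 0.0149). The immediate early transcription factor Egr1 fell by 2.93 ± 0.24 (adjusted p = 0.00341). Further falls were those of Sgms2, a sphingomyelin synthase (-2.88), the lymphatic chemokine Ccl21 (-2.70), Cryl1 (-2.49) and Iqcm (-1.84) (adjusted p = 0.0114, 0.0154, 0.00466 and 0.032). Rab18 and the M-band protein gene Myom2 fell as well, each with a difference of -1.62, and Tmem179 fell 2.83-fold (adjusted p = 0.0491, 0.0233 and 0.0452). Nppa, the atrial natriuretic peptide gene, differed by -1.38 ± 0.62, skeletal actin Acta1 by -0.99 ± 0.22 and the stress-responsive Ankrd1 by -0.61 ± 0.21, none of which passed (adjusted p = 0.492, 0.181 and 0.383). The matrix genes Col1a1, Col3a1, Fn1 and Postn had differences of 0.97, 1.02, 0.93 and 1.74 and did not pass either (adjusted p = 0.311, 0.208, 0.36 and 0.245). Tgfb2 differed by -0.64, Ccn2 by -0.13, Timp1 by 0.38 and Spp1 by -0.11 (adjusted p = 0.443, 0.875, 0.603 and 0.91), and Atp2a2 was at the ceiling on all arrays. Postn, Tgfb2, Timp1 and Spp1 lay in the background in every group, so the sizes of their differences are not measured in any comparison. In all, limma called 59 of 23188 rows, 44 higher and 15 lower on the TAC arrays, of which 44 were named, and 2393 rows had an unadjusted p under 0.05 against 1159 by chance. All 59 had both TAC arrays on 1 side of both normal arrays, as did 43.3% of all rows (33.3% by chance). Of the called rows 30 were dim, below the 95th percentile of the negative controls, Lgals5, Alox15, Chrna1, Ephx2, Sgms2 and Ccl21 among them. Most of all tested rows were dim as well, with a median row mean of 5.32 against a percentile of 8.18. In 24 of the named calls both arrays of a group lay below their own array's percentile, and the difference is then only a bound, as for Alas2, Slc4a1, Usp18, Lgals5, Ephx2 and Wfdc1. In 14 of the 24 the mean of the brighter group lay below the mean percentile of its own or of the dimmer group's arrays. The size of the difference is then not measured, as for Alox15, Fgf7, Chrna1, Irf7, Mx1, Cnn1, Sgms2 and Ccl21. The last 3 had a group below the median of the controls. No call passed in every fit that left out 1 array: limma called 0 rows without TAC replicate 2 (2025 at an unadjusted p under 0.05), 7 without normal replicate 1, 12 without TAC replicate 1, 13 without normal replicate 2 and 35 without either TAC-R array. The count was 170 with an intensity trend in the moderation, 39 with control rows kept in, 35 with only the 2 groups in the fit, and 353 at an unadjusted p under 0.05 with a 2-fold minimum.

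Of 54 gene lists, camera placed 9 higher and 5 lower on the TAC arrays than on the normal arrays. Of the erythroid markers, 4 of 9 measured genes rose, 0 fell and 5 did not pass, with 8 higher when adjusted over the list alone and a mean difference of 1.76 (adjusted p = 5.77e-17, and adjusted p = 0.364 with an estimated correlation). Hbb, another beta-globin gene, rose by 1.82 ± 0.22 (adjusted p = 0.0165), and Hba-a1, alpha-globin, was at the ceiling on both TAC arrays, at least 1.71-fold above the normal arrays (adjusted p = 0.262). Of the interferon response list, 4 of 21 genes rose and 17 did not pass, with 15 higher and 1 lower when adjusted over the list alone (mean 0.99, adjusted p = 4.56e-15, and adjusted p = 0.364 with an estimated correlation). Its leading members were Usp18 (2.12 ± 0.22, adjusted p = 0.00818), Ifi27 (2.21 ± 0.27, adjusted p = 0.0165), the transcription factor gene Irf7 (1.61 ± 0.21, adjusted p = 0.0191) and the antiviral GTPase gene Mx1 (2.05 ± 0.28, adjusted p = 0.0309). Of the macrophage and monocyte markers, 0 of 23 passed alone and 2 were higher when adjusted over the list alone (mean 0.50, adjusted p = 8.58e-07, and adjusted p = 0.364 with an estimated correlation), led by Cd68 at 1.52 ± 0.25 (adjusted p = 0.0709).

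Some lists of connective tissue were also placed higher on the TAC arrays, with few members passing alone. Basement membrane genes, myofibroblast markers and matrix metalloproteases and inhibitors were not called (adjusted p = 0.663, 0.113 and 0.414). Of 17 fibroblast markers 0 passed, and 7 were higher when adjusted over the list alone (mean 0.52, adjusted p = 3.4e-05). Of 28 matricellular and fibrosis genes 0 passed, and 10 were higher and 1 lower when adjusted over the list alone (mean 0.41, adjusted p = 0.00055). Of 18 genes of fibrillar collagens and their processing 0 passed, and 5 were higher when adjusted over the list alone (mean 0.39, adjusted p = 0.0034). With an estimated correlation each of these 3 lists had an adjusted p = 0.561. Of 15 pericyte and smooth muscle markers 1 rose, the smooth muscle gene Cnn1 by 1.65 ± 0.23 at signals in the background (adjusted p = 0.0319), and 2 were higher when adjusted over the list alone (mean 0.43, adjusted p = 0.0115). Pericyte and smooth muscle markers had an adjusted p = 0.561 with an estimated correlation. Of 30 fatty acid oxidation genes 0 passed, and 4 were higher when adjusted over the list alone (mean 0.24, adjusted p = 0.0115, and adjusted p = 0.561 with an estimated correlation), led by the thioesterase gene Acot2 at 1.28 ± 0.23 (adjusted p = 0.101). Of 22 TGF-beta and BMP signalling genes 0 passed, and 0 did when adjusted over the list alone (mean 0.24, adjusted p = 0.0409). TGF-beta and BMP signalling genes had an adjusted p = 0.518 with an estimated correlation. The TGF-beta and BMP signalling list lost its call without either normal array or either TAC array (adjusted p = 0.0956 and 0.0762 without normal replicates 1 and 2, 0.0847 and 0.111 without TAC replicates 1 and 2). The fatty acid oxidation list lost it without TAC replicate 2 (0.111), and the pericyte and smooth muscle markers without normal replicate 1 or TAC replicate 1 (0.0554 and 0.154).

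Among the lists lower on the TAC arrays, 2 of 14 natriuretic and fetal cardiac genes fell, Nppb and Myh7, and 12 did not pass. When adjusted over the list alone 5 were lower (mean -0.57, adjusted p = 0.000285, and adjusted p = 0.367 with an estimated correlation). Of 23 immediate early genes 1 fell, Egr1, and 4 were lower when adjusted over the list alone (mean -0.40, adjusted p = 0.000347). Immediate early genes had an adjusted p = 0.561 with an estimated correlation. Fos and Jun had differences of -1.38 ± 0.36 and -0.73 ± 0.21 (adjusted p = 0.262 and 0.311). Of 17 glucocorticoid response genes 0 passed, and 1 was lower when adjusted over the list alone (mean -0.31, adjusted p = 0.0034). Glucocorticoid response genes had an adjusted p = 0.367 with an estimated correlation. Of 6 lymphatic markers 1 fell, Ccl21, and 3 were lower when adjusted over the list alone (mean -0.82, adjusted p = 0.00764). Lymphatic markers had an adjusted p = 0.561 with an estimated correlation. Lyve1, a hyaluronan receptor of lymphatic vessels, differed by -1.64 ± 0.26 (adjusted p = 0.0574). Of 14 skeletal muscle markers 0 passed, and 2 were lower when adjusted over the list alone (mean -0.32, adjusted p = 0.0034). Skeletal muscle markers had an adjusted p = 0.367 with an estimated correlation. Of the 14 list calls, 0 passed with an estimated correlation in camera (6 of 54 lists at an unadjusted p under 0.05), 2 passed in fry, those of the erythroid markers (adjusted p = 0.0102) and the interferon response (0.014), and 9 passed whichever array was left out. The lymphatic markers lost their call on ranks (adjusted p = 0.34) and without normal replicate 1 (0.0554), and the skeletal muscle markers without TAC replicate 2 (0.0506).

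**Figure D1:**
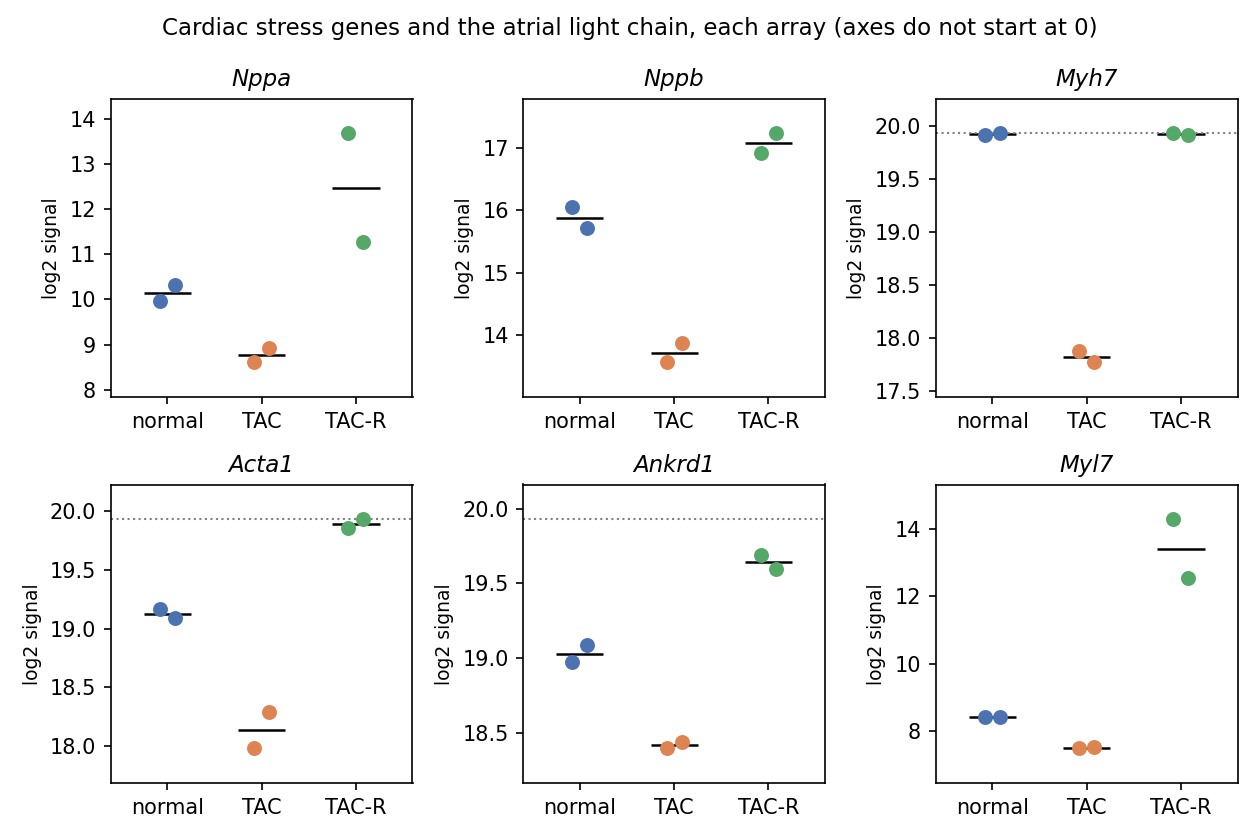
Log2 signal of Nppa, Nppb, Myh7, Acta1, Ankrd1 and Myl7 on each of the 6 arrays (points) by group, with the group means as lines, the ceiling as a dotted line where it lies near, and axes that do not start at 0. The 2 TAC arrays were lowest for Nppb, at 13.57 and 13.88, and for Myh7, and the 2 TAC-R arrays differed from each other in Myl7 (14.30 and 12.54) and Nppa (13.69 and 11.26).

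The second comparison asked how hearts released from TAC differed from hearts still under it. On the arrays labelled TAC-R, atrial myosin light chain, natriuretic peptide B, slow myosin and skeletal actin transcripts rose, and Fgf7, Igf1, Igf2, Col3a1, Col1a2, Hbb-b1 and Hbb-bs fell. Myl7, the atrial regulatory light chain, was at least 38.03-fold higher at 13.42 ± 1.25 against 7.49 ± 0.02 log2 units (mean ± SD, n = 2 each, adjusted p = 0.00315), with 14.30 and 12.54 on the 2 TAC-R arrays and a TAC signal below the 95th percentile of the negative controls. This bound is for the mean of the 2 TAC-R arrays, and TAC-R replicate 2 alone would give a smaller one. Nppb rose by 3.35 ± 0.24 log2 units, 10.2-fold (adjusted p = 0.00204), Myh7 by 2.10 ± 0.20 (adjusted p = 0.00663) and Acta1 by 1.76 ± 0.22 (adjusted p = 0.0157), and for Myh7 and Acta1 these are lower bounds because 1 TAC-R array was at the ceiling. Fgf7, a growth factor made by mesenchymal cells, fell by 4.14 ± 0.24, from 8.17 ± 0.33 to 4.03 ± 0.04 (adjusted p = 0.000994). Its TAC-R signal lay below the median of the negative controls, 4.47, and only 1 TAC array was above the 95th percentile, so the size of this difference is not measured. The growth factor genes Igf2 and Igf1 fell, with differences of -2.82 ± 0.39 and -1.56 ± 0.25 (adjusted p = 0.0269 and 0.0438).

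Of the fixed matrix genes, Col3a1 fell by 1.72 ± 0.24 and fibronectin, Fn1, fell by 1.78 ± 0.29 (adjusted p = 0.0269 and 0.0496). Col1a1 differed by -1.59 ± 0.28 and Postn by -1.70 ± 0.43 and did not pass (adjusted p = 0.0607 and 0.184). Nppa differed by 3.71 ± 0.62 and Ankrd1 by 1.23 ± 0.21, both close to the threshold and not past it (adjusted p = 0.0527 and 0.0515). Tgfb2 differed by 1.25, Ccn2 by 0.10, Timp1 by -0.28 and Spp1 by -0.77 (adjusted p = 0.102, 0.907, 0.73 and 0.251), and Atp2a2 was at the ceiling. The relaxin receptor gene Rxfp1 rose by 3.22, Sgms2 by 3.16, Cryl1 by 3.11, the sarcomeric Ankrd23 by 3.05, Aif1l by 2.90 and Ccl21 by 2.72 (adjusted p = 0.00718, 0.00718, 0.00204, 0.00416, 0.00204 and 0.0151). Tceal7 and Cdhr5 rose by 2.50 and 2.44 (adjusted p = 0.0107 and 0.0215). Epha3, an ephrin receptor, fell, as did Hbb-b1, Ephx2, Alox15 and Hbb-bs, with differences of -3.05, -2.75, -2.59, -2.36 and -2.07 (adjusted p = 0.00338, 0.00416, 0.0107, 0.00968 and 0.0151). Retsat, Agpat3 and Cdh13 fell, with differences of -2.03, -2.03 and -2.02 (adjusted p = 0.0081, 0.0148 and 0.0151). In all, limma called 100 rows, 52 higher and 48 lower on the TAC-R arrays, of which 77 were named, and 2547 rows had an unadjusted p under 0.05 against 1159 by chance. All 100 had both TAC-R arrays on 1 side of both TAC arrays, as did 40.5% of all rows (33.3% by chance), and 40 were dim, among them Fgf7, Epha3, Rxfp1, Sgms2, Ankrd23, Ccl21, Tceal7, Cdhr5, Ephx2 and Alox15. Both arrays of a group lay below their array's 95th percentile of the negative controls in 36 of the named calls, which gives only a bound, as for Myl7, Rxfp1, Ankrd23, Ephx2, Slc4a1, Lyve1, Zbtb16, Mt2A and Col15a1. In 21 of the 36 the size is not measured, since the mean of the brighter group did not pass the floor either, among them Fgf7, Sgms2, Ccl21, Epha3, Ifit1, Alox15, Cdhr5 and Tceal7, the first 5 with a group below the median of the controls. Aif1l, Cryl1, Fgf7 and Nppb were the 4 calls that passed whichever array was left out, and the count fell to 4 without TAC replicate 2, 9 without TAC replicate 1, 14 without TAC-R replicate 2, 16 without TAC-R replicate 1 and 37 without either normal array. It was 344 with an intensity trend (141 higher and 203 lower), 187 with rows below the median of means left out (79 and 108), 44 with control rows kept in (29 and 15), 37 with only the 2 groups in the fit (24 and 13), and 456 at an unadjusted p under 0.05 with a 2-fold minimum (172 and 284). Which direction had more calls therefore depends on the setting.

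Camera placed 5 lists higher and 16 lower on the TAC-R arrays than on the TAC arrays. Of 17 fibroblast markers 2 fell, Col3a1 and Col1a2, 15 did not pass, and 13 were lower when adjusted over the list alone (mean -0.91, adjusted p = 2.07e-11). Fibroblast markers had an adjusted p = 0.26 with an estimated correlation. Col1a2, the other chain of type I collagen, fell by 1.66 ± 0.27 (adjusted p = 0.0469). Of 28 matricellular and fibrosis genes 1 fell, Fn1, and 14 were lower when adjusted over the list alone (mean -0.69, adjusted p = 8.06e-11, and adjusted p = 0.26 with an estimated correlation), among them the small proteoglycan gene Lum at -1.24 ± 0.25 (adjusted p = 0.104). Of 18 genes of fibrillar collagens and their processing 2 fell, and 6 were lower when adjusted over the list alone (mean -0.66, adjusted p = 4.39e-07). Fibrillar collagens and their processing had an adjusted p = 0.328 with an estimated correlation. Of 10 basement membrane genes 1 fell, Col15a1 at -1.69 ± 0.26 (adjusted p = 0.0418), and 7 were lower when adjusted over the list alone (mean -0.77, adjusted p = 4.39e-07). Basement membrane genes had an adjusted p = 0.328 with an estimated correlation. Of 15 pericyte and smooth muscle markers 0 passed, and 8 were lower when adjusted over the list alone (mean -0.65, adjusted p = 5.27e-07). Pericyte and smooth muscle markers had an adjusted p = 0.26 with an estimated correlation. Of 22 TGF-beta and BMP signalling genes 1 fell, Fstl1 at -1.68 ± 0.24 (adjusted p = 0.0286), and 1 was higher and 4 lower when adjusted over the list alone (mean -0.40, adjusted p = 0.000438). TGF-beta and BMP signalling genes had an adjusted p = 0.26 with an estimated correlation. Of 15 myofibroblast markers 1 fell, Fn1, and 3 were lower when adjusted over the list alone (mean -0.44, adjusted p = 0.00944). Myofibroblast markers had an adjusted p = 0.57 with an estimated correlation. Of 33 growth factors of hypertrophy 1 fell, Igf1, and 4 were lower when adjusted over the list alone (mean -0.28, adjusted p = 0.0136). Growth factors of hypertrophy had an adjusted p = 0.548 with an estimated correlation. The myofibroblast markers lost their call without TAC replicate 2 or TAC-R replicate 2 (adjusted p = 0.0627 and 0.4), and the growth factors of hypertrophy without TAC-R replicate 2 (0.448).

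Of the blood, immune and vessel lists some were placed lower on the TAC-R arrays and the lymphatic markers higher. Not called were the neutrophil, T and NK cell, B and plasma cell, platelet and MHC class II lists (adjusted p = 0.871, 0.729, 0.0652, 0.576 and 0.871). Of 9 erythroid markers 2 fell, Hbb-b1 and Slc4a1, the latter at -1.84 ± 0.21 (adjusted p = 0.014), and 6 were lower when adjusted over the list alone (mean -1.07, adjusted p = 7.51e-09). Erythroid markers had an adjusted p = 0.26 with an estimated correlation. Alas2 differed by -1.32 ± 0.22 and did not pass (adjusted p = 0.0538). Of 21 interferon response genes 1 rose, Ifit1 by 2.27 ± 0.28 at signals in the background (adjusted p = 0.0157), although the list lay lower, with 1 higher and 6 lower when adjusted over the list alone (mean -0.41, adjusted p = 6.89e-05). Interferon response genes had an adjusted p = 0.26 with an estimated correlation. Of 23 macrophage and monocyte markers 0 passed, and 4 were lower when adjusted over the list alone (mean -0.35, adjusted p = 0.000957). Macrophage and monocyte markers had an adjusted p = 0.272 with an estimated correlation. Of 16 endothelial markers 0 passed, and 0 did when adjusted over the list alone (mean -0.40, adjusted p = 0.000493). Endothelial markers had an adjusted p = 0.356 with an estimated correlation. Of 35 cell cycle genes 0 passed, and 2 were lower when adjusted over the list alone (mean -0.30, adjusted p = 0.000438, and adjusted p = 0.26 with an estimated correlation), with the proliferation marker Mki67 at -1.03 ± 0.25 (adjusted p = 0.16). Of 24 hypoxia and angiogenesis genes 1 fell, the apelin receptor gene Aplnr at -1.34 ± 0.21 (adjusted p = 0.0439), which was also the 1 lower when adjusted over the list alone (mean -0.26, adjusted p = 0.0101). Hypoxia and angiogenesis genes had an adjusted p = 0.328 with an estimated correlation. Of 15 complement genes 0 passed, and 0 did when adjusted over the list alone (mean -0.27, adjusted p = 0.0367). Complement genes had an adjusted p = 0.328 with an estimated correlation. Of 30 fatty acid oxidation genes 0 passed, and 5 were lower when adjusted over the list alone (mean -0.22, adjusted p = 0.0119). Fatty acid oxidation genes had an adjusted p = 0.39 with an estimated correlation. The hypoxia and angiogenesis list lost its call without TAC replicate 2 or TAC-R replicate 2 (adjusted p = 0.0732 and 0.0694), fatty acid oxidation without TAC replicate 2 or TAC-R replicate 1 (0.0732 and 0.0598), and complement without TAC replicate 1, TAC replicate 2 or TAC-R replicate 2 (0.0642, 0.0857 and 0.189).

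Among the 5 lists higher on the TAC-R arrays, 3 of 14 natriuretic and fetal cardiac genes rose, Nppb, Myh7 and Acta1. When adjusted over the list alone 6 were higher and 2 lower (mean 0.83, adjusted p = 8.78e-05, and adjusted p = 0.26 with an estimated correlation). Of 17 glucocorticoid response genes 3 rose, the metallothionein gene Mt2A by 1.65 ± 0.22, Zbtb16 by 1.72 ± 0.23 and the clock gene Per1 by 1.82 ± 0.29 (adjusted p = 0.023, 0.0248 and 0.0446). In that list 5 were higher and 1 lower when adjusted over the list alone (mean 0.45, adjusted p = 0.00125). Glucocorticoid response genes had an adjusted p = 0.26 with an estimated correlation. Of 6 lymphatic markers 2 rose, Ccl21 and Lyve1, the latter by 2.10 ± 0.26 (adjusted p = 0.0157), and 2 were higher when adjusted over the list alone (mean 0.92, adjusted p = 0.00155). Lymphatic markers had an adjusted p = 0.39 with an estimated correlation. Of 17 heat shock proteins 0 passed, and 0 did when adjusted over the list alone (mean 0.30, adjusted p = 0.000957). Heat shock proteins had an adjusted p = 0.26 with an estimated correlation. Of 27 genes of oxidative stress and NRF2 targets 2 rose, Mt2A and Ncf1, a subunit of the phagocyte oxidase (2.36 ± 0.22, adjusted p = 0.00582), and 4 were higher and 1 lower when adjusted over the list alone (mean 0.20, adjusted p = 0.0442). Oxidative stress and NRF2 targets had an adjusted p = 0.39 with an estimated correlation. Of the 21 list calls, 0 passed with an estimated correlation in camera (10 of 54 lists at an unadjusted p under 0.05), 1 passed in fry, that of the erythroid markers (adjusted p = 0.0468), and 15 passed whichever array was left out. The call for oxidative stress and NRF2 targets was lost without either normal array (adjusted p = 0.0602 each), without TAC replicate 1 (0.214) and without TAC-R replicate 1 (0.33). On ranks it was lost too (0.134), as were those of the growth factors of hypertrophy and the lymphatic markers (0.0675 each).

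**Figure D2:**
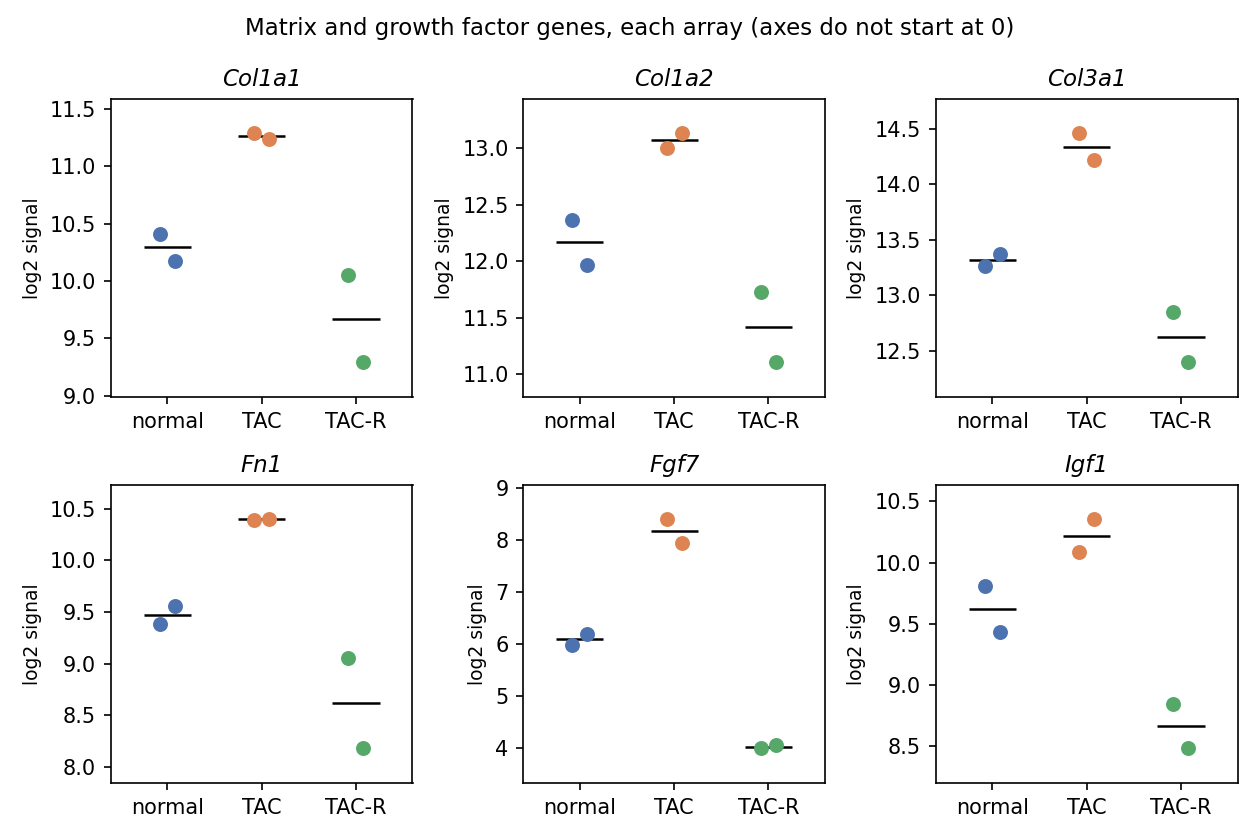
Log2 signal of the matrix genes Col1a1, Col1a2, Col3a1 and Fn1 and the growth factor genes Fgf7 and Igf1 on each of the 6 arrays (points) by group, with the group means as lines and axes that do not start at 0. Fgf7 averaged 6.09 on the normal arrays, 8.17 on the TAC arrays and 4.03 on the TAC-R arrays, and Col3a1 averaged 13.32, 14.34 and 12.62.

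The last comparison asked how hearts released from TAC differed from normal hearts. On the arrays labelled TAC-R, Myl7, Chrna1 and Ncam1 rose against the normal arrays, and the immediate early genes Egr1 and Dusp1, Ccn1 and Fgf7 fell. Myl7 was at least 30.3-fold higher, at 13.42 ± 1.25 against 8.41 ± 0.02 log2 units (mean ± SD, n = 2 each, adjusted p = 0.0105), with 14.30 and 12.54 on the 2 TAC-R arrays. The bound is again for the mean, and TAC-R replicate 2 alone would give a smaller one. Chrna1 rose by 3.88 ± 0.26 from a normal signal of 5.15 ± 0.15, below the 95th percentile of the negative controls (adjusted p = 0.00223), and Ncam1, the neural cell adhesion molecule, by 2.96 ± 0.28 (adjusted p = 0.011). Egr1 fell by 3.96 ± 0.24, 15.5-fold, from 13.81 ± 0.27 to 9.86 ± 0.18 (adjusted p = 0.00158). The matricellular gene Ccn1 fell by 2.14 ± 0.22 and the phosphatase gene Dusp1 fell by 1.65 ± 0.22 (adjusted p = 0.013 and 0.0493). Fgf7 fell by 2.06 ± 0.24 (adjusted p = 0.0242), with both groups in the background, so that the size is not measured.

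The interferon-induced genes Ifi27 and Ifi27l2b rose by 2.54 and 1.96, Aif1l by 2.43, Ankrd23 by 2.39, Cpxm2 by 2.12, Cyp4v3 by 1.79 and Alas2 by 1.70 (adjusted p = 0.0185, 0.0493, 0.0075, 0.0207, 0.0493, 0.0493 and 0.0493). Vamp1, a protein of vesicle fusion, fell by 2.02 and Retsat fell by 1.58 (adjusted p = 0.0207 and 0.0493), and no further named gene was called lower. Nppa differed by 2.33 ± 0.62, Nppb by 1.19 ± 0.24, Acta1 by 0.77 ± 0.22 and Ankrd1 by 0.61 ± 0.21, and none passed (adjusted p = 0.288, 0.17, 0.305 and 0.358). For Myh7 the difference of 0 is truncated, since 1 array of each group was at the ceiling, and Atp2a2 was at it throughout. Col1a1, Col3a1, Fn1 and Postn differed by -0.62, -0.70, -0.85 and 0.04 (adjusted p = 0.473, 0.371, 0.373 and 0.986). Tgfb2, Ccn2, Timp1 and Spp1 differed by 0.61, -0.03, 0.11 and -0.88 (adjusted p = 0.441, 0.98, 0.909 and 0.278). In all, limma called 21 rows, 14 higher and 7 lower on the TAC-R arrays, of which 17 were named, and 2478 rows had an unadjusted p under 0.05 against 1159 by chance. All 21 had both TAC-R arrays on 1 side of both normal arrays, as did 40.9% of all rows (33.3% by chance), and 9 were dim, Chrna1, Ankrd23, Cpxm2, Ifi27l2b and Fgf7 among them. Both arrays of a group lay below their array's 95th percentile of the negative controls in 10 of the named calls, which gives only a bound for Myl7, Chrna1, Ankrd23, Vamp1 and Cyp4v3. In 5 of the 10, those of Alas2, Ifi27l2b, Cpxm2, Irf7 and Fgf7, the size is not measured. For Cpxm2, Irf7 and Fgf7 both groups lay below the percentile of their own arrays. For Alas2 and Ifi27l2b the TAC-R signals lay above the percentile of their own arrays, but their mean was below that of the normal arrays. No call passed in every fit that left out 1 array: limma called 0 rows without normal replicate 2 (1630 at an unadjusted p under 0.05), 1 without normal replicate 1, 2 without TAC-R replicate 1, 7 without TAC-R replicate 2 and 12 without either TAC array. The count was 156 with an intensity trend, 68 with rows below the median of means left out, 54 with each array centred on its median, 37 with the rows at the ceiling on all arrays left out, 10 with control rows kept in, 12 with only the 2 groups in the fit, and 331 at an unadjusted p under 0.05 with a 2-fold minimum.

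Camera placed 6 lists higher and 9 lower on the TAC-R arrays than on the normal arrays. Of 21 interferon response genes 2 rose, Ifi27 and Irf7, the latter by 1.64 ± 0.21 (adjusted p = 0.0437), and 6 were higher when adjusted over the list alone (mean 0.58, adjusted p = 2.45e-06). Interferon response genes had an adjusted p = 0.534 with an estimated correlation. Of 9 erythroid markers 1 rose, Alas2, and 5 were higher when adjusted over the list alone (mean 0.69, adjusted p = 1.78e-05). Erythroid markers had an adjusted p = 0.534 with an estimated correlation. Of 13 atrial markers 1 rose, Myl7, and 5 were higher when adjusted over the list alone (mean 0.95, adjusted p = 0.00409). Atrial markers had an adjusted p = 0.534 with an estimated correlation and 0.0842 on ranks, with a median of 0.34. Relative to their mean over the 6 arrays they lay at 1.05 on TAC-R replicate 1, 0.249 on TAC-R replicate 2 and -0.332 and -0.271 on the normal arrays. Without TAC-R replicate 1 their adjusted p was 0.0346. Of 17 heat shock proteins 0 passed, and 1 was higher when adjusted over the list alone (mean 0.35, adjusted p = 0.00119, and adjusted p = 0.534 with an estimated correlation), with Hspb1 at 1.08 ± 0.25 (adjusted p = 0.225). Of 17 genes of branched-chain amino acid breakdown 0 passed, and 2 were higher when adjusted over the list alone (mean 0.34, adjusted p = 0.00393, and adjusted p = 0.534 with an estimated correlation). The leading member was Bdh1 at 1.49 ± 0.22 (adjusted p = 0.0756), the enzyme of ketone body use named above. The list therefore does not measure branched-chain breakdown alone. Of 23 genes of atrophy, proteasome and autophagy 0 passed, and 0 did when adjusted over the list alone (mean 0.20, adjusted p = 0.0338). Atrophy, proteasome and autophagy had an adjusted p = 0.534 with an estimated correlation. The list of branched-chain amino acid breakdown lost its call without TAC-R replicate 2 (adjusted p = 0.0628), and that of atrophy, proteasome and autophagy without normal replicate 2 or TAC-R replicate 2 (0.267 and 0.169).

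Among the lower lists, 2 of 23 immediate early genes fell, Egr1 and Dusp1, and 1 was higher and 7 lower when adjusted over the list alone (mean -0.63, adjusted p = 2.02e-06, and adjusted p = 0.534 with an estimated correlation). Of 10 basement membrane genes 0 passed, and 6 were lower when adjusted over the list alone (mean -0.64, adjusted p = 2.39e-06, and adjusted p = 0.534 with an estimated correlation), with Nid2 at -1.08 ± 0.25 (adjusted p = 0.225). Of 16 endothelial markers 0 passed, and 3 were lower when adjusted over the list alone (mean -0.44, adjusted p = 3.53e-05, and adjusted p = 0.534 with an estimated correlation), with the receptor gene Kdr at -0.99 ± 0.25 (adjusted p = 0.259). Of 17 fibroblast markers 0 passed, and 0 did when adjusted over the list alone (mean -0.40, adjusted p = 0.000322). Fibroblast markers had an adjusted p = 0.534 with an estimated correlation. Of 28 matricellular and fibrosis genes 1 fell, Ccn1, the 1 that was also lower when adjusted over the list alone (mean -0.28, adjusted p = 0.00393). Matricellular and fibrosis genes had an adjusted p = 0.534 with an estimated correlation. Of 18 genes of fibrillar collagens and their processing 0 passed, and 0 did when adjusted over the list alone (mean -0.28, adjusted p = 0.0145). Fibrillar collagens and their processing had an adjusted p = 0.557 with an estimated correlation. Of 24 hypoxia and angiogenesis genes 0 passed, and 1 was higher and 2 lower when adjusted over the list alone (mean -0.23, adjusted p = 0.015). Hypoxia and angiogenesis genes had an adjusted p = 0.534 with an estimated correlation. Of 15 pericyte and smooth muscle markers 0 passed, and 1 was higher and 1 lower when adjusted over the list alone (mean -0.23, adjusted p = 0.0304). Pericyte and smooth muscle markers had an adjusted p = 0.534 with an estimated correlation. Of 7 conduction system markers 0 passed, and 1 was higher and 3 lower when adjusted over the list alone (mean -0.42, adjusted p = 0.0388, and adjusted p = 0.534 with an estimated correlation). Tbx18 differed by -1.48 ± 0.22 (adjusted p = 0.0756) at signals in the background, so the size is not measured. Of the 15 list calls, 0 passed with an estimated correlation in camera (3 of 54 lists at an unadjusted p under 0.05), 0 passed in fry (11 lists at an unadjusted p under 0.05), and 7 passed whichever array was left out. Without TAC-R replicate 2, camera called 7 lists, and the calls were lost for fibrillar collagens and their processing (adjusted p = 0.459), matricellular and fibrosis genes (0.457), conduction system markers (0.316), pericyte and smooth muscle markers (0.316), hypoxia and angiogenesis (0.0994) and fibroblast markers (0.0908). Without normal replicate 2 the calls for fibrillar collagens and their processing (0.0695), hypoxia and angiogenesis (0.134), conduction system markers (0.0898) and pericyte and smooth muscle markers (0.0837) were lost, and without normal replicate 1 those for conduction system markers (0.0799) and pericyte and smooth muscle markers (0.0588). The conduction system markers were not called on ranks either (0.235).

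**Figure D3:**
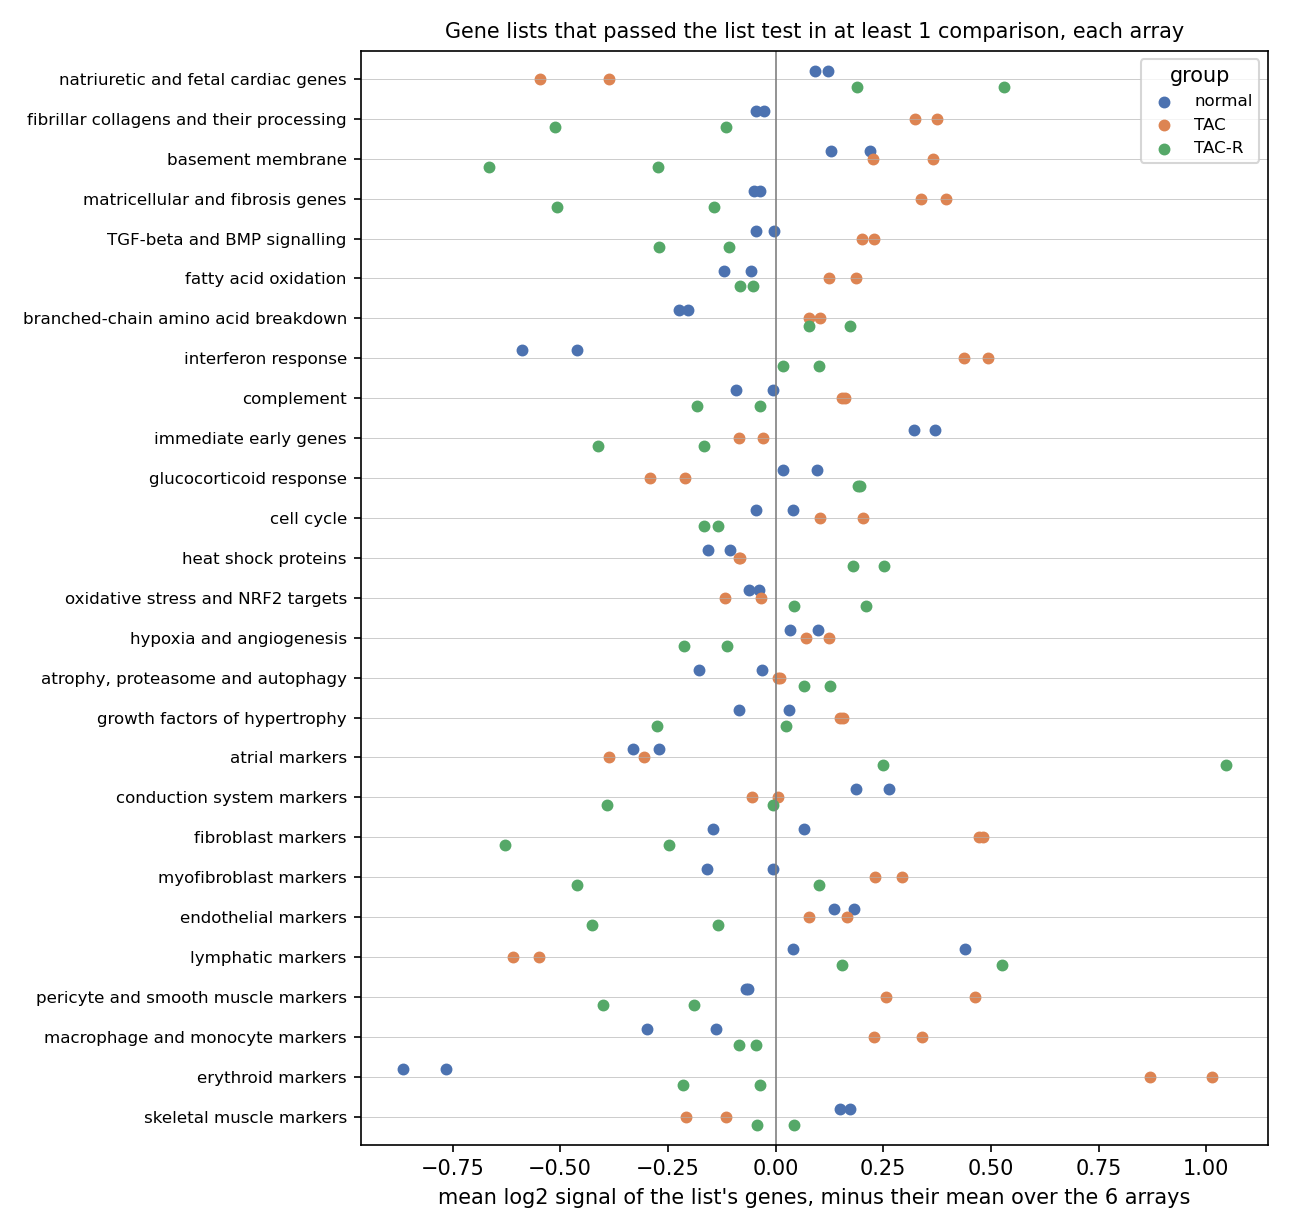
Mean log2 signal of the measured genes of each of the 27 lists that passed in at least 1 comparison, minus their mean over the 6 arrays, with 1 point per array coloured by group. The erythroid markers lay between -0.866 and -0.765 on the normal arrays and between 0.869 and 1.01 on the TAC arrays, and the fibroblast markers between -0.628 and -0.248 on the TAC-R arrays.

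Calls were then set side by side across comparisons. Of the rows called in TAC against normal, 11 rose and were lower again in TAC-R than in TAC, among them Agpat3, Alox15, Ephx2, Fgf7, Hbb-b1, Hbb-bs and Slc4a1. A further 7 fell and were higher again in TAC-R, namely Ccl21, Cryl1, Iqcm, Myh7, Nppb, Sgms2 and Tmem179. That makes 18 calls in opposite directions and 0 in the same direction. Independent lists would share 0.125 opposite calls, which leaves out that both comparisons use the same TAC arrays. Groups simulated on shared arrays shared 0 in 20 draws, which leaves out the effects, so the excess over either is not taken as a shared effect. Against normal hearts, 7 rows were higher both in TAC and in TAC-R, among them Alas2, Chrna1, Cyp4v3, Ifi27, Ifi27l2b and Irf7, and 2 were lower in both, Egr1 and an unnamed row. These 9 compare with 0.0311 and 0 in the same 2 ways, with the same limits. Fgf7 was the 1 gene called in opposite directions against normal, higher in TAC and lower in TAC-R. Across rows, the covariance of TAC minus normal with TAC-R minus TAC was -0.0802 against -0.0353 from shared arrays alone, and that of TAC minus normal with TAC-R minus normal was 0.0671 against 0.0354. The correlations were -0.528 against -0.5 and 0.462 against 0.501 from shared arrays alone. The shared group has only 2 arrays and could not be split into parts of at least 2, so part of each overlap may come from the shared arrays.

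For the rows that differed most between TAC and normal arrays, the TAC-R minus normal slope was 39.2% of the TAC minus normal slope. The share of 0.392 had a range of 0.370 to 0.426 over the 4 ways of choosing the selecting pair. Both slopes use the same normal arrays, so a difference peculiar to the normal arrays counts as remaining. Groups that differ in unrelated ways would leave a share too, and its size was not worked out. The share therefore does not show how much of an effect of TAC persisted. This share describes these 6 arrays and has no test.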

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

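The tests without the rows at the ceiling on all arrays and with the control rows kept in were chosen only after the results were seen, and all others were planned. Counts of genes changed are given in the order TAC against normal, TAC-R against TAC and TAC-R against normal, where they were 59, 100 and 21. They moved to 170, 344 and 156 with an intensity trend in the moderation. With the replicate number as a block they were 36, 47 and 11, although the numbers do not pair the arrays: the deviations of equally numbered arrays from their group means correlated at 0.0117, -0.00932 and -0.0127. With rows below the median of means left out the counts were 87, 187 and 68, with each array centred on its median 84, 144 and 54, and with only the 2 groups compared 35, 37 and 12. At an unadjusted p under 0.05 with a 2-fold minimum they were 353, 456 and 331. Left without the rows at the ceiling the test gave 78, 143 and 37, where the prior rose from 5.71 to 7.11 degrees of freedom. With the control rows kept in they were 39, 44 and 10, with a prior of 4.40. Leaving out 1 array, which makes the lone array of a group vary like the others by assumption, gave 0 to 35, 4 to 37 and 0 to 12, with fewer arrays in each fit. The cause of the other moves was not tested. Counts stayed within 1.5 times of these under the robust fit (74, 128 and 22), the filter at the 25th percentile (60, 122 and 21), quantile normalization again (56, 101 and 19), array weights (70, 95 and 14) and a 2-fold minimum added to the adjusted p (59, 100 and 21).

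The lists shifted numbered 14, 21 and 15. With an estimated correlation camera called 0, 0 and 0 of them, at an unadjusted p under 0.05 in 6, 10 and 3 lists, and fry called 3, 2 and 0, including the cardiomyocyte markers, which camera did not call. These are other tests of the same values. The estimated correlation also missed the shift planted in simulated arrays, but the genes there were independent of each other. In TAC-R against TAC, heat shock proteins had an estimated correlation of 0.0104, near the preset. Their unadjusted p in camera still went from 0.000217 to 0.0345, since that test uses only the 3 residual degrees of freedom. A call lost in it therefore does not show that correlation between genes made the call. In the real lists the estimated correlations ran from -0.0925 (Schwann and nerve markers) to 0.521 (myofibroblast markers), against the preset 0.01. They were 0.280 for the erythroid markers and 0.0600 for the interferon response. The simulation therefore cannot decide between the tests for correlated lists. Leaving out 1 array gave 11 to 14, 17 to 24 and 7 to 19 lists, and the replicate block gave 14, 20 and 14. Ranks, the filter, quantile normalization again and the fit without the rows at the ceiling gave 14 to 15, 19 to 23 and 13 to 17. The remaining share of 0.392 moved to 0.328 with rows below the median of means left out, for a cause that was not tested, and lay between 0.374 and 0.406 under the other settings, at 0.378 to 0.406 when 1 TAC-R array was left out. Of 249 results for named genes, 79 passed. None of the 79 reversed its direction in the fits run for named genes, which were the trend, robust, block, normalization, ceiling and control row fits and those without 1 array. Of the results that did not pass, up to 7 changed sign, without normal replicate 2. The replicate block and the control rows each ended 28 of those calls, quantile normalization again ended 4, and leaving out 1 array ended from 47 to 66. No filter on signal over background was applied in the reported counts, and 30, 40 and 9 of the called rows lay below the 95th percentile of the negative controls. Most of all tested rows lay below it too.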

Other observations

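Here the tests of a wrong label on a single array, of exchanged TAC and TAC-R labels and of scaling were chosen only after the result was seen, and the genes named in the next paragraph were picked after their values were seen. The tests of atrial tissue and blood were chosen before.

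Further genes were called. On the arrays labelled TAC, interferon-induced genes outside the fixed list rose against normal arrays, namely Oas1b by 2.32 ± 0.27, Oas2 by 1.94 ± 0.23 and Lgals3bp by 1.62 ± 0.25 log2 units (limma, adjusted p = 0.0119, 0.0154 and 0.0491). Apoe, the apolipoprotein that macrophages secrete, rose by 1.97 ± 0.22, the mitochondrial carrier gene Ucp2 by 2.02 ± 0.24, and Car2, a carbonic anhydrase abundant in red cells, by 1.70 ± 0.20 (adjusted p = 0.0119, 0.0143 and 0.0154). On the arrays labelled TAC-R, Rcan1, a target of calcineurin, rose against TAC by 1.37 ± 0.20, the Z-disc gene Tcap by 1.62 ± 0.24, the monoamine oxidase gene Maoa by 2.29 ± 0.23 and the hyaluronidase gene Hyal1 by 1.97 ± 0.21 (adjusted p = 0.0366, 0.036, 0.00796 and 0.00951). Col6a2, a chain of type VI collagen, the matrix gene Efemp1 and Gpc3, a cell surface proteoglycan, fell, with differences of -1.66 ± 0.23, -1.94 ± 0.31 and -1.71 ± 0.22 (adjusted p = 0.0257, 0.0446 and 0.0171). Both groups lay below the 95th percentile of the negative controls for Oas1b, Oas2 and Gpc3, so the size of these differences is not measured, and the dimmer group did for Car2, Col6a2 and Efemp1, whose differences are only bounds. None of the calls in this paragraph passed whichever array was left out: without TAC replicate 2, limma called 0 rows in TAC against normal (2025 at an unadjusted p under 0.05) and 4 others in TAC-R against TAC.

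Several lists did not pass in camera. Of 36 oxidative phosphorylation genes 0 passed in each comparison, also when adjusted over the list alone, with mean differences of -0.02, 0.06 and 0.05 for TAC against normal, TAC-R against TAC and TAC-R against normal (adjusted p = 0.695, 0.409 and 0.713). Of 38 cytosolic ribosomal proteins 0 passed in each, also when adjusted over the list alone, with means of 0.06, 0.05 and 0.11 (adjusted p = 0.796, 0.437 and 0.233). Of 13 neutrophil markers 0 passed in each (adjusted p = 0.849, 0.871 and 0.943), and when adjusted over the list alone 0, 0 and 2 did. Of 18 T and NK cell markers 0 passed in each (adjusted p = 0.585, 0.729 and 0.792), and when adjusted over the list alone 3, 1 and 1 did. The cardiomyocyte markers were not called in camera (adjusted p = 0.255, 0.253 and 0.955), while fry gave adjusted p = 0.00648 for a mean of -0.14 in TAC against normal and 0.00455 for a mean of 0.16 in TAC-R against TAC, and Tcap was the 1 of 15 that rose. Of the 15, Myl3, Pln and Mb were at the ceiling on all arrays and show no change or spread, so this fry result is not read further. When adjusted over the list alone, 1, 1 and 0 cardiomyocyte markers passed.

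Nppb and Myh7 fell in the arrays labelled TAC and rose in those labelled TAC-R, and Acta1 rose in the latter, although load on the heart is known to raise these genes. A scaling shift shared by all signals could not be tested, since RMA makes the distributions of the arrays alike and the spikes were normalized with them. The spikes added at hybridization (bioB, bioC, bioD and cre) had a mean TAC minus normal difference of 0.0588 ± 0.0902. That of Nppb, Myh7 and Acta1 was -1.75 ± 0.108. The spikes thus show no shift at their own signals, between 8.96 and 13.28. No spike was as bright as these genes, so a shift among the brightest signals stays open. A wrong label on a single array is argued against by 0 of the 6 arrays correlating best with an array of another group. The margin was narrow for TAC-R replicate 1, at 0.9913 with its own group against 0.9907 with normal replicate 1. An exchange of the TAC and TAC-R labels as whole groups cannot be told apart from a true difference: on the arrays labelled TAC-R, the mean of Nppb and Acta1 lay 0.979 ± 0.144 above normal (truncated, with 1 TAC-R array at the ceiling for Acta1, and without Myh7, at the ceiling in both groups) while the fibrillar collagens lay at -0.276 ± 0.198, which such an exchange would place above normal. Exchanges of whole groups that involve the normal labels were not tested and stay open. A true effect of TAC and of its release, the biological difference that the design names, stays open and untested.

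Myl7 and Nppa differed between the 2 TAC-R arrays, at 14.30 and 12.54 and at 13.69 and 11.26, and lay above normal on both. A candidate explanation is more atrial tissue in the TAC-R samples, and 3 further atrial genes, Sln, Myl4 and Bmp10, had a mean TAC-R minus normal difference of 1.37 ± 0.82. Sln (6.10 and 4.07) and Myl4 (8.72 and 5.91) were higher on TAC-R replicate 1, as Myl7 and Nppa were, while Bmp10 differed by 0.34, and apart from Myl4 on replicate 1 all 3 had signals below the 95th percentile of the negative controls on every array, so their size is not measured and the test leaves atrial tissue open. The 11 atrial markers without Myl7 and Nppa, these 3 included, lay above normal by a median of 0.192 on TAC-R replicate 1 and 0.181 on TAC-R replicate 2, with means of 0.736 and 0.175. On the normal and TAC arrays Myl7 lay between 7.48 and 8.43, below each array's 95th percentile of the negative controls. Nppa lay above it on these arrays. The label whole heart therefore does not show how much atrial tissue the normal and TAC samples held. Atrial tissue and a change within the ventricle after release cannot be told apart here.

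Erythroid transcripts were higher on the TAC arrays, with a mean difference of 2.79 ± 0.145 for Alas2, Slc4a1 and Hbb-b1. More whole blood left in the TAC hearts may add to this, and the neutrophil and platelet genes S100a8, S100a9, Pf4 and Ppbp had a mean difference of 0.307 ± 0.298. S100a8, S100a9 and Ppbp (0.231, 1.15 and -0.319) had signals below the 95th percentile of the negative controls, where a rise can be hidden, and Pf4 differed by 0.167 at signals above it, but is 1 gene. Retained blood, younger red cells in the blood and other differences between TAC and normal animals cannot be told apart with these arrays.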
